A study of Oryza sativa with 6 samples.

How the data were processed

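Dual-colour microarrays compared rice plants (Oryza sativa cv. Nipponbare) that carry a Tos17 retrotransposon insertion in the gene of cytosolic glutamine synthetase 1;1 (GS1;1) with wild-type plants. GS1;1 joins ammonium to glutamate to make glutamine. Seedlings grew in hydroponic solution with ammonium chloride at 1 mM and were harvested on day 18 after sowing, per the labels. Leaf blade, leaf sheath and root were measured separately. Leaf material came from 4 plants, per the series description, which speaks of a single plant for the roots and leaves open whether that holds for each root sample. The sample labels name leaf 3 and the series description names leaf 4, and the sources used here do not settle which was taken. Each hybridization started from 750 ng of total RNA, per the labels.

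Each organ had 2 arrays that form a dye swap, 6 arrays in all. The mutant RNA was in Cy5 on replicate 1 and in Cy3 on replicate 2, per the labels. Ratios of replicate 2 were turned, so every ratio below is mutant over wild type. The labels do not say that the swapped arrays used other RNA extracts. The 2 arrays of an organ were therefore averaged to 1 replicate, and no p-value was computed within an organ from independent plants. All 6 arrays were used, and 0 columns were left without a sample.

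Each array held 22575 spots, of which 21495 were gene probes, each named by a different full-length cDNA. The deposited scanner output gives the mean foreground intensity and the local background intensity of each spot in both dyes, without normalization. It was made with Agilent Feature Extraction A.7.5.1, per the file headers. Processed intensities in the deposited output had passed spatial detrending, dye normalization with LOWESS parameters and the scanner program's error model, per the file headers. The deposited log10 ratio of each spot is processed Cy5 over processed Cy3. The deposited series table matched that log10 ratio (r = 1 on the replicate 1 arrays and -1 on the replicate 2 arrays), so it holds log10 mutant over wild type. Its medians on replicates 1 and 2 were 0.00498 and -0.000367 in leaf blade, 0.000517 and -0.00136 in leaf sheath, and 2.64e-06 and 0 in root. Spot marks for saturation, outlying pixels and signal above background are other values that the deposited output carries.

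The ratios reported here were recomputed from the foreground and background intensities as log2 values with limma 3.58.1 in R 4.3.3, with data.table at version 1.17.8. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Spots marked as outliers were set to missing, which removed 7 to 161 gene spots per array. Saturated spots were kept, 20 to 48 per array in red and 2 to 6 in green. A gene was tested in an organ where its signal was well above background in the same genotype on both arrays. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

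Signal over background takes the place of depth on these arrays. Green signal was above background for 86.5% to 95.7% of gene spots, and red signal for at least 93.4%. Median green foreground was 215.8 to 330.7 units, and median red foreground was 314.4 to 704.4 units. Negative control spots had medians of 84.38 to 166.8 units in green and 68.54 to 88.4 units in red. The number of arrays limits the precision of every value.

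Within an organ, a gene was called higher or lower by a size rule, an absolute log2 ratio of at least 1 in the same direction on both arrays. Errors within an organ are the SD of the 2 arrays. A common effect over the 3 organ averages was tested with limma's moderated statistic and Benjamini-Hochberg adjustment at 0.05, and its errors are SE. A secondary limma fit treated the 6 arrays as separate samples, with a term per organ and a dye term, and tested differences between organs. That fit has 2 residual degrees of freedom and its spread is the spread between arrays, which the labels do not assign to different plants. The organ average and this fit were chosen before the data were examined, as were the 32 gene lists, the naming rule and most of the alternatives.

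Gene lists were built from words in the probe descriptions, which name the best database match and often another species. Of the 28 rice loci written beside the lists, 0 could be joined to a cDNA name, so description words alone decided membership. The rule for the genes named below took all members of the 5 nitrogen lists by this route. It also took the 10 highest and 10 lowest called genes with a named product per organ, the highest and lowest member of each list described plus up to 2 called members, and the 5 largest differences in each direction per pair of organs. The cDNA names matched 0 entries of the RefSeq gene table used, so no chromosome positions are given. A list's median in an organ was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal, where the list had at least 5 measured members. These percentiles treat genes as independent and describe these arrays only. For the common effect, lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each over 32 lists.

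The steps were tested on simulated data. For the size rule and the fit on single arrays, simulated arrays differed by their own spread alone, with no added spread between plants. Their counts of unchanged genes called are therefore no error rates for an effect of the genotype. For the common effect, the simulated organs also differed as in the measured averages. For root, with 20333 genes, the size rule recovered 0% of genes changed by 0.5 or 1, 92% of those changed by 1.5 and 98% of those changed by 2 on the log2 scale, and called 0 unchanged genes. The fit on single arrays recovered 70%, 94%, 100% and 94% of those sizes in root, with 2 unchanged genes called among 20291. For the difference between root and leaf blade it recovered 36%, 68%, 84% and 80%, with 1 unchanged gene called among 18655. The common effect recovered 0%, 56%, 80% and 72% after adjustment, with 2 unchanged genes called among 18574. Without adjustment it recovered 88%, 100%, 100% and 100%, with 982 unchanged genes below 0.05.

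Alternatives covered background correction, normalization, the signal filter, outlier marks, the deposited processed intensities and series table, quantile scaling of the mean signals, the dye term, variance moderation, the size rule and leaving out each array. The 6 arrays lie on 6 slides and were processed on 2 days. Both leaf blade arrays share one day, and the leaf sheath and root arrays share the other. Each ratio is formed within an array. Differences between leaf blade and the other organs cannot be told apart from a difference between days.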

Results

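Transcript ratios of GS1;1 mutant over wild-type rice were measured in leaf blade, leaf sheath and root, with 2 arrays per organ and the dyes exchanged between them. After the signal filter, 19116 genes were measured in leaf blade, 20062 in leaf sheath and 20333 in root. Values are log2 ratios of mutant over wild type with the SD of the 2 arrays, unless another error is named. Each organ has 1 biological average, so calls within an organ rest on size and carry no p-value. Ratios of the 2 arrays correlated across genes at r = 0.423 in leaf blade, 0.473 in leaf sheath and 0.533 in root. The median SD was 0.109, 0.088 and 0.093 in that order.

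The array has a probe (AK109397) described as shoot cytosolic glutamine synthetase, taken here as the gene disrupted in the mutant. Its ratio was -0.005 ± 0.016 in leaf blade, -0.14 ± 0.05 in leaf sheath and 0.06 ± 0.05 in root. The 2 arrays gave -0.016 and 0.007 in leaf blade, -0.177 and -0.101 in leaf sheath, and 0.09 and 0.025 in root. None of these passed limma on single arrays, with adjusted p of 0.948, 0.0895 and 0.349. The probe's signal was 1.18 to 3.32 times the 95th percentile of the negative controls. Where the probe lies relative to the insertion is not given in the sources used here, so it checks no label, and all directions below rest on the labels.

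In leaf blade, where the question was how the loss of GS1;1 alters leaf transcripts, 43 genes were higher and 115 lower in the mutant, 0.827% of those measured. The early light-inducible protein AK062972, a chlorophyll-binding protein of stressed thylakoids, was highest among genes with a named product at 3.10 ± 0.14, an 8.55-fold ratio. A cytochrome P450 (AK067007) was lowest at -2.83 ± 0.11, and its best match is an Arabidopsis abscisic acid hydroxylase. Next among named products came the photosystem II 10 kD protein AK062172 at -2.82 ± 0.28 and the homeodomain leucine zipper gene Oshox6 (AK063685) at -2.45 ± 0.16. Peroxiredoxin Q (AK059845), a chloroplast antioxidant enzyme, was higher at 1.46 ± 0.03, and chalcone synthase (AK067810), the entry enzyme of flavonoid synthesis, was higher at 1.43 ± 0.03.

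Other genes higher in leaf blade were the calcium-binding protein HRA32 (AK099476) at 1.80 ± 0.08, aldehyde dehydrogenase ALDH1a (AK105638) at 1.64 ± 0.03 and nucleoside diphosphate kinase (AK072751) at 1.43 ± 0.05. Genes lower in leaf blade included the Ve1-like resistance gene AK108785 at -2.32 ± 0.08, the receptor kinases AK111620 at -2.09 ± 0.06 and AK100394 at -1.86 ± 0.08, and the bacterial-induced peroxidase AK067000 at -1.96 ± 0.08. The Clp protease subunit AK068727 was lower at -2.04 ± 0.18, the ankyrin-kinase AK100268 at -1.99 ± 0.18 and ribosome-inactivating protein 2 (AK103707) at -1.84 ± 0.19.

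The Calvin cycle list in leaf blade held 0 called genes, 1 higher without replicate 1, and 1 higher and 2 lower without replicate 2. The 23 measured Calvin cycle genes had a median of 0.215, at percentile 100 of random lists and 0.478 without replicate 1, from a Rubisco small subunit (AK099574) at 0.98 to another (AK070556) at -0.54. Genes of chlorophyll and tetrapyrrole synthesis had a median of 0.197, also at percentile 100 and 0.124 without background subtraction, with 0 of 14 called. Photorespiration genes had a median of 0.10, at percentile 99.35 and 0.161 with median centring, and glycine decarboxylase subunit H (AK062851) stood at 1.00 ± 0.12. Light reaction genes split, with probes of PsbS, needed for dissipating excess light energy, at 1.25 ± 0.21 (AK071638) and 1.21 ± 0.08 (AK058284), and a light-harvesting protein (AK061619) at -1.52 ± 0.30. Their median of -0.056 turned positive with median centring, which left 0 of them called, and without replicate 1, while 3 were lower without replicate 2.

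Trehalose genes were lower in leaf blade in 2 of 13 cases, with trehalose-6-phosphate synthase-like AK072066 at -1.45 ± 0.19 and AK067731 at -1.20 ± 0.11, while AK067066 stood at 0.58. Their median was -0.119, at percentile 0.83, and ranged from -0.386 with processed intensities to -0.074 without background subtraction. It was -0.246 without replicate 2, where 4 were lower, and 1 was lower with median centring. WRKY transcription factors, regulators of defence, had a median of -0.106 at percentile 0.06, -0.178 with processed intensities and -0.174 without replicate 2, with 0 of 24 called, against 1 and 2 lower under those settings, AK110587 the lowest and AK061266 the highest at 0.83. Phenylpropanoid genes had 2 of 60 lower, 4-coumarate-CoA ligase AK068985 at -1.42 ± 0.01 and hydroxycinnamoyl transferase AK060705 at -1.20 ± 0.04, a number that 7.77% of random lists reached, against 1 with median centring and 0 without background subtraction. Their median was 0.029, at percentile 93.83. Of the 158 calls, 156 also passed limma on single arrays, and 2 were not in that fit. The fit uses the same arrays, so a call by size nearly fixes this outcome, which is no separate support. Deposited processed intensities gave 92 higher and 220 lower genes, and median centring gave 25 and 68. Without replicate 1 the counts were 116 and 133, and without replicate 2 they were 56 and 249.

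**Figure D1:**
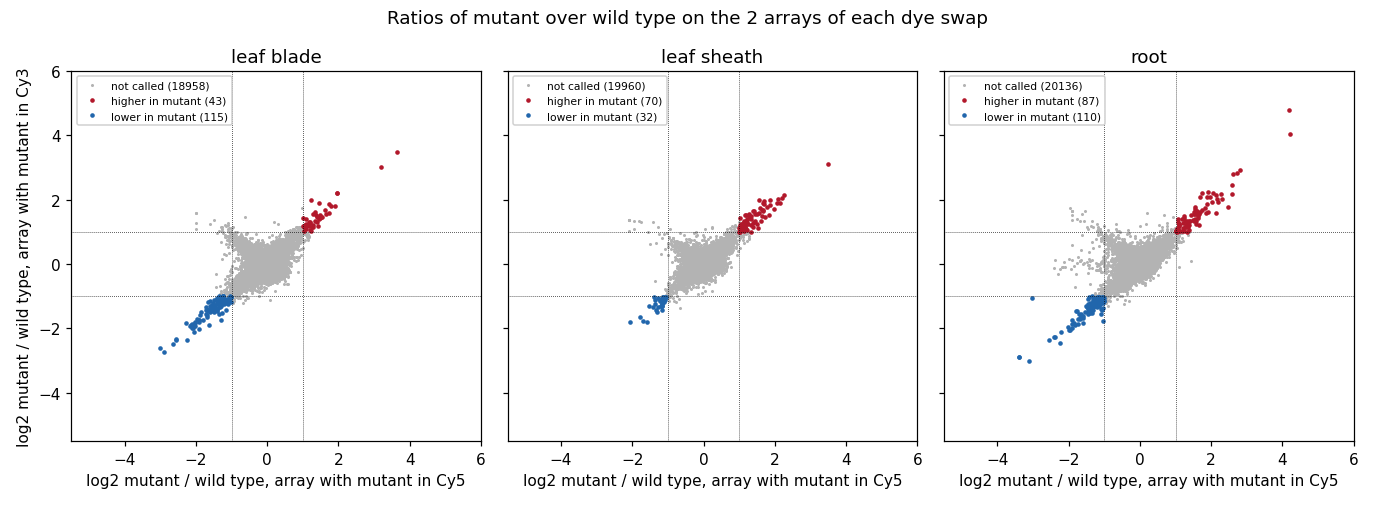
Each point is a gene, with its log2 mutant over wild type on replicate 1 against replicate 2 in each organ, and called genes are coloured. Across all measured genes the 2 arrays correlated at 0.423 in leaf blade, 0.473 in leaf sheath and 0.533 in root.

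In leaf sheath, 70 genes were higher and 32 lower in the mutant, 0.508% of the genes measured. Beta-expansin EXPB3 (AK100959), a wall-loosening protein and the highest gene with a named product, stood at 2.04 ± 0.05 and EXPB11 (AK059638) at 1.67 ± 0.11. The cellulose synthases CesA-9 (AK072356) and CesA-7 (AK073561) stood at 1.56 ± 0.02 and 1.36 ± 0.24. In all, 6 of 74 expansin and wall synthesis genes were higher, a number that 0% of random lists reached, and 0 were lower. Without background subtraction 3 were higher. Beta tubulin (AK065323), a microtubule protein, was higher at 1.93 ± 0.09.

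Phenylpropanoid genes were higher in leaf sheath in 3 of 66 cases, a number that 0.08% of random lists reached. These were phenylalanine ammonia-lyase, the entry enzyme of the pathway, at 1.66 ± 0.03 (AK100346) and 1.14 ± 0.03 (AK068993), and a caffeic acid O-methyltransferase (AK064768) at 1.39 ± 0.08. Chalcone synthase AK067810 was higher at 1.85 ± 0.04 and cadinene synthase AK071447, a sesquiterpene enzyme, at 1.98 ± 0.14. Peroxidases went both ways, with 3 of 77 higher, among them AK106200 at 1.77 ± 0.30 and pox2 (AK061809) at 1.67 ± 0.23, and 3 lower, among them POX22.3 (AK073202) at -1.73 ± 0.10 and POX8.1 (AK101772) at -1.24 ± 0.07. Without background subtraction 2 were higher and 1 lower.

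Probenazole-inducible PBZ1 (AK071613), a pathogenesis-related protein, was lower in leaf sheath at -1.73 ± 0.05, as were a thaumatin-like protein (AK111104) at -1.42 ± 0.16 and a chitinase (AK060033) at -1.07 ± 0.01. With these, 3 of 97 genes of pathogenesis-related proteins and chitinases were lower and 1 (AK103755, 1.09) was higher, against 6 lower with processed intensities, 5 lower without replicate 2 and 2 lower without background subtraction. The higher call was lost with median centring and without background subtraction. The P450 AK067007 was lowest at -1.95 ± 0.18, and the receptor kinase AK111620 stood at -1.69 ± 0.14. The alpha-galactosidase SIP (AK067229) was lower at -1.31 ± 0.03, and the transporter PDR1 (AK105311) at -1.26 ± 0.07.

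Median ratios of leaf sheath lists were 0.132 for Calvin cycle genes, at percentile 99.96, 0.125 for photorespiration genes, at percentile 99.7 and 0.213 without replicate 1, and 0.107 for chlorophyll and tetrapyrrole genes, at percentile 99.49 and 0.171 without replicate 2. None of these 3 lists held a called gene, while without replicate 1 or replicate 2 the Calvin cycle list held 4 higher or 4 lower ones. Medians were -0.165 for trehalose genes, at percentile 0.02 and -0.261 without replicate 2, and -0.101 for WRKY factors, at percentile 0.01. The median of 139 ribosomal protein genes was -0.047, at percentile 0, and turned positive with median centring. Of the 102 calls, 98 also passed limma on single arrays, 2 did not, and 2 were not in that fit. As in leaf blade, the fit reuses the same arrays and is no separate support. Deposited processed intensities gave 124 higher and 61 lower genes, and intensities without background subtraction gave 40 and 17. Without replicate 1 there were 107 higher genes, and without replicate 2 there were 72 lower genes.

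In root, 87 genes were higher and 110 lower in the mutant, 0.969% of those measured. Transporters of ammonium and nitrate were higher in 3 of 20 cases, a number that 0% of random lists reached, and in 1 case with median centring. Probes of the ammonium transporter OsAMT1 stood at 1.88 ± 0.02 (AK107204) and 1.33 ± 0.04 (AK073718). These share a description and may not be separate genes. The nitrate transporter Nrt2 (AK072215) stood at 1.03 ± 0.01. Glutamate dehydrogenases, which release or bind ammonium, were lower in the forms GDH2 (AK063467) at -1.80 ± 0.08 and GDH1 (AK065301) at -1.11 ± 0.03, and median centring left 1 lower gene on that list. In the same roots, the 9 root organ markers had a median of -0.254, at percentile 0.08 and -0.384 with processed intensities, and RCc3 (AK062381) was lower at -1.13 ± 0.09, a call lost with median centring.

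The transporter list had a median of 0.183 in root, at percentile 100, with a further Nrt2 probe (AK109733) at 0.69 ± 0.08, an NRT1.1-like nitrate transporter (AK070077) at 0.81 ± 0.04 and the lowest member (AK107190) at -0.42 ± 0.24. A further probe with the OsAMT1 description (AK107601) stood at 0.23 ± 0.06. In leaf blade and leaf sheath 0 transporters were called, and OsAMT1 probe AK107204 stood at 0.09 ± 0.32 and -0.05 ± 0.23. The OsAMT1 probe AK073718 stood at 0.61 ± 0.02 in leaf blade and 0.19 ± 0.05 in leaf sheath. Nitrate reductase, which turns nitrate into nitrite, was higher in root for AK102363 at 1.13 ± 0.14 and in leaf blade for AK102178 at 1.03 ± 0.03, and median centring left neither call. Leaf sheath showed AK102363 at -0.60 ± 0.04. NADH-dependent glutamate synthase (AK070485), which pairs with glutamine synthetase, stood at -0.91 ± 0.10 in leaf blade, -0.76 ± 0.03 in leaf sheath and -0.01 ± 0.03 in root, below the size rule in each.

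Other glutamine synthetase genes stayed below the size rule. Chloroplast glutamine synthetase (AK063706) stood at 0.73 ± 0.12 in leaf blade, 0.36 ± 0.04 in leaf sheath and 0.15 ± 0.02 in root. The gene gs1-2 (AK063913) stood at -0.03, 0.05 and 0.04 in that order. Of the 6 probes on that list, AK061951 and AK065125 are glutamine tRNA synthetases that the description words also matched. Asparagine synthetase, which makes the storage amide asparagine, ranged over both probes (AK100247 and AK101821) from -0.02 to 0.20. The list of asparagine and aspartate genes held 0 called genes in all 3 organs. The GDH list in root had a median of -0.014 with a mean of -0.42, and a further GDH probe (AK071839) stood at -0.61 ± 0.01. The GDH probes AK101492 and AK067680 stood at 0.06 and -0.01 in root. The last one, AK103028, did not pass the signal filter in root, so its -0.08 is not part of that median and mean.

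**Figure D2:**
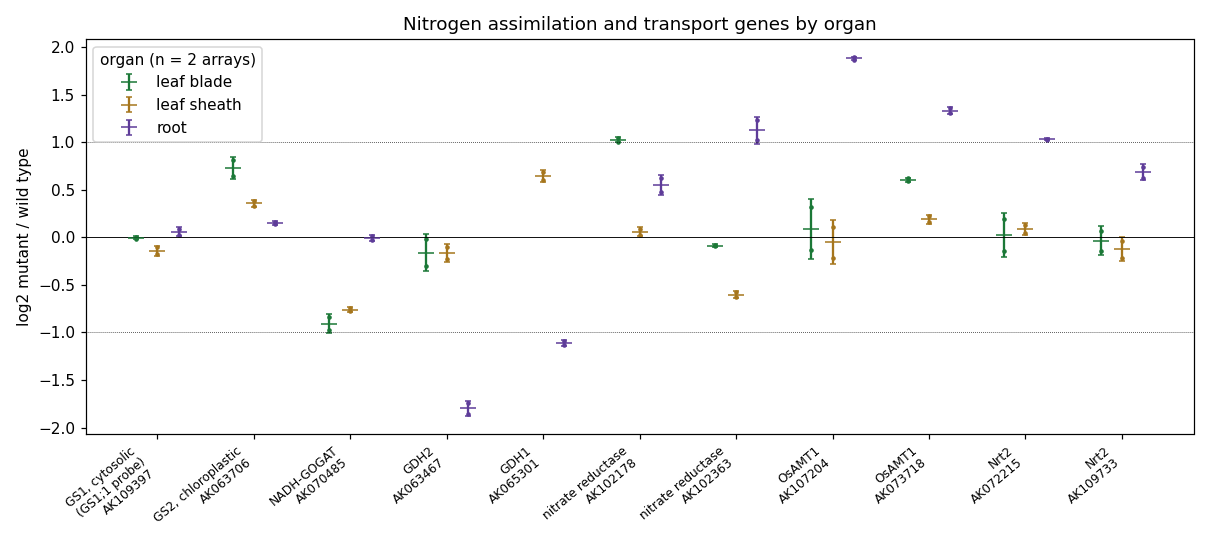
Log2 ratio of mutant over wild type for genes of nitrogen uptake and assimilation in each organ, with the 2 arrays as points around their mean. OsAMT1 reached 1.88 and GDH2 reached -1.80 in root.

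Transporters of sulfate and phosphate were among the 10 highest named root genes. The sulfate transporter Sultr1-1 (AK103007) stood at 2.14 ± 0.11 and a high affinity phosphate transporter (AK108907) at 2.09 ± 0.10. Purple acid phosphatase PAP22 (AK073222) stood at 1.63 ± 0.02, and 2 of 39 phosphate starvation genes were higher with 0 lower. An aquaporin (AK107700), a water channel, was higher at 1.07 ± 0.06, and the aquaporin list had a median of 0.139 at percentile 98.86, with 0 called under median centring and a median of 0.032 without replicate 2. Tricarboxylic acid cycle genes had a median of 0.124 at percentile 100, with 0 of 39 called. The 100 genes with the largest excess of signal in root over leaf blade had a median of -0.236 in these roots, and 3 of them were higher and 10 lower.

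The highest named root genes were DDTFR19 (AK062386) at 2.86 ± 0.08, ribosomal protein S6 (AK109085) at 2.77 ± 0.07, an aldolase (AK104952), a glycolytic enzyme, at 2.70 ± 0.12 and ubiquitin-S27a (AK103890) at 2.23 ± 0.08. Of 141 ribosomal protein genes 3 were higher, although the list's median was -0.042 and its mean 0.021. The lowest named gene was thionin Osthi1 (AK062831), an antimicrobial peptide, at -3.06 ± 0.08. Arginine decarboxylase (AK058573), which starts polyamine synthesis, stood at -2.35 ± 0.16, fatty acid alpha-oxidase (AK100592) at -2.35 ± 0.11, nodulin-35 (AK071410), a uricase, at -2.01 ± 0.08 and lipoxygenase L-2 (AK073529) at -1.88 ± 0.04.

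Wall genes were lower in root in 5 of 78 cases and higher in 0, with a list median of 0.015 at percentile 80.94 that turned negative with median centring and without replicate 2. Among the lower ones were the endoxyloglucan transferases AK101915 at -1.61 ± 0.03 and AK061093 at -1.46 ± 0.02, which rebuild wall xyloglucan, and 0.01% of random lists had as many lower. Peroxidases were lower in 3 of 81 cases, among them AK073833 at -1.42 ± 0.04 and AK103558 at -1.29 ± 0.02, and in 1 case with median centring. Pathogenesis-related and chitinase genes were lower in 5 of 105 cases, among them a PR-1-type gene (AK060005) at -1.41 ± 0.53, and higher in 2, PBZ1 at 1.71 ± 0.05 and a glucanase (AK104862) at 1.58 ± 0.01. With median centring that list had 1 lower and 3 higher genes, and without replicate 2 it had 8 lower. These 3 groups lie beside the root marker median of -0.254 in the same RNA. Trehalose genes had a median of -0.217 at percentile 0, with AK101245 at -1.11 ± 0.03, a call lost with median centring. All 197 root calls also passed limma on single arrays, which reuses the same arrays and is no separate support. Median centring left 69 lower genes, without replicate 1 there were 144 higher genes, and without replicate 2 there were 250 lower genes.

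**Figure D3:**
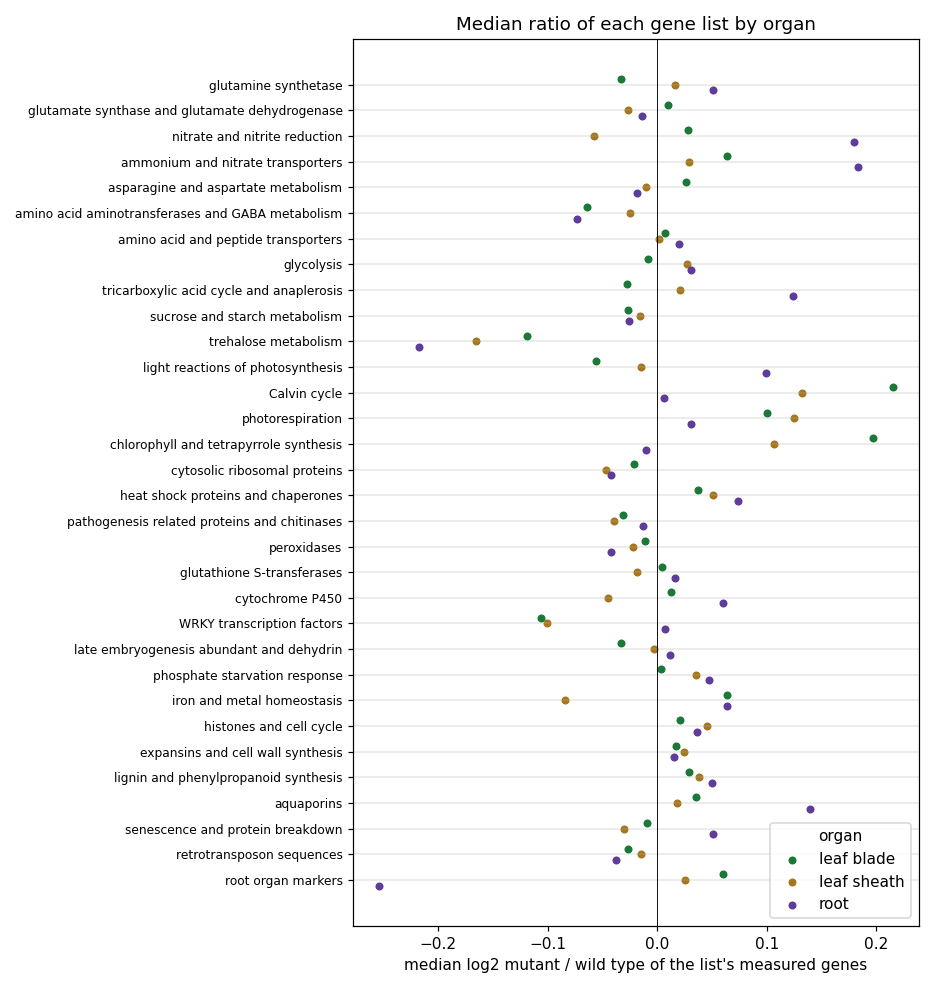
Median log2 ratio of mutant over wild type of each of the 32 gene lists, with 1 point per organ. Root organ markers lie at -0.254 and ammonium and nitrate transporters at 0.183 in root, and Calvin cycle genes lie at 0.215 in leaf blade.

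Genes called the same way in all 3 organs numbered 3. GAL83 (AK068637), a beta subunit of the SnRK1 energy-sensing kinase, was lower at -1.33 ± 0.12 in leaf blade, -1.18 ± 0.16 in leaf sheath and -1.21 ± 0.13 in root. A flavonoid glycosyltransferase (AK071127) was higher at 1.60 ± 0.07, 1.24 and 1.15. A transcript of unknown product (AK102606) was higher at 1.496, 2.19 and 4.12. GAL83 and AK102606 were chosen for naming after their values were seen. Leaf blade and leaf sheath shared 6 higher and 9 lower genes, where independent lists would share 0.134 and 0.194. Leaf blade and root shared 3 and 6, against 0.161 and 0.56, and leaf sheath and root shared 6 and 8, against 0.274 and 0.154.

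Averaged ratios correlated across genes, which are not independent replicates, at r = 0.364 between leaf blade and leaf sheath. They correlated at 0.202 between leaf blade and root and at 0.146 between leaf sheath and root. Single arrays of different organs correlated at 0.285 to 0.505 with the same dye orientation and at -0.054 to 0.043 with the opposite one.

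The common effect of the mutant over the 3 organs was tested in 18574 genes, and limma with Benjamini-Hochberg adjustment called 0 risen and 0 fallen. At an unadjusted p under 0.05 there were 1822 genes, 761 up and 1061 down, where chance gives 929. With trend and robust options in limma's variance moderation there were 115, fewer than chance gives. GAL83 had the smallest adjusted p in limma, 0.305, with -1.24 ± 0.054 (SE, n = 3 organs) and the same sign in 3 organs. The flavonoid glycosyltransferase AK071127 stood at 1.33 ± 0.106 (SE) with an adjusted p of 0.365 in limma. With the 6 arrays as separate samples and a dye term, 202 genes rose and 303 fell. That fit counts the dye-swapped arrays of an organ as independent, which the labels do not show, so its counts are no test over separate plants.

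Some genes passed when adjusted over the list alone, and for each of these lists the count over all genes was 0. That adjustment leaves the choice among 32 lists uncorrected, and 4 lists held such a gene. Adjusted over the list alone, 4 trehalose genes fell, led by AK100050 at -0.76 ± 0.153 (SE) with a limma adjusted p of 0.041. AK105417, AK067731 and AK105382 among them share a description, so they may not be separate genes. Adjusted over the list alone, 3 genes of the Calvin cycle list rose, and each is described as a Rubisco subunit binding-protein. AK061410 among them stood at 0.65 ± 0.073 (SE) with a limma adjusted p of 0.0157. No Rubisco subunit rose by this count. The Calvin cycle list also had 4 that fell, the Rubisco small subunit AK070556 at -0.40 and the large subunit probes AK058516 at -0.38, AK062203 at -0.43 and AK058623 at -0.39. These large subunit probes were saturated in red on every leaf array, and their leaf values had SDs of 0.253 to 2.45 between the 2 arrays, larger than the effect in all but leaf blade AK058516. WRKY gene AK061266 rose by 0.74 ± 0.103 (SE), against its list's median of -0.087, and a Bowman-Birk protease inhibitor (AK067257) of the pathogenesis-related list fell by 0.71 ± 0.063 (SE), both adjusted over the list alone. The genes named from these counts were chosen after their values were seen.

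Across all 3 organs, camera with its preset correlation called trehalose genes down at an adjusted p of 0.00441, with a median of -0.16. It called photorespiration genes up, ribosomal protein genes down and heat shock genes up, each at an adjusted p of 0.0174, and WRKY factors down at 0.0328. Each of these 5 lists had an adjusted p = 0.58 by camera with an estimated correlation, so 0 of 32 lists passed. The estimates were -0.061 for trehalose, -0.003 for heat shock, 0.014 for ribosomal protein, 0.103 for WRKY and 0.32 for photorespiration genes. For trehalose and heat shock genes they lay below the preset, so a larger correlation cannot explain that change. With an estimated correlation, camera also refers its statistic to the 2 residual degrees of freedom that the organ averages leave. The camera settings therefore differ in more than the correlation. With the preset, camera gave ribosomal protein genes an adjusted p of 0.782 with median centring and 0.067 with processed intensities. By fry, 0 lists moved one way, with a smallest adjusted p of 0.206 for trehalose genes, while 8 lists passed its test for changes in either direction. That test asks whether a list's members change, not whether they change more than other genes. Lignin and phenylpropanoid genes had the smallest adjusted p of that test, 0.00211.

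Differences between organs in the mutant's effect were tested with limma on single arrays, where 2609 genes differed between leaf sheath and leaf blade, 4801 between root and leaf blade and 4072 between root and leaf sheath. PBZ1 (AK071613) differed most between root and leaf sheath, by 3.45 ± 0.043 (SE, adjusted p = 0.00124 by limma), from -1.73 in leaf sheath to 1.71 in root. A disease resistance response gene (AK106022) went the other way, by -3.24 ± 0.148 (SE), from 1.56 in leaf sheath to -1.68 in root. The ratio of the aldolase AK104952 was higher in root than in leaf blade by 3.13 ± 0.048 (SE). That of thionin Osthi1 was lower in root by -3.09 ± 0.066 (SE). The ratio of Oshox6 was higher in leaf sheath than in leaf blade by 2.20 ± 0.055 (SE). That of the early light-inducible protein was lower in leaf sheath by -2.27 ± 0.122 (SE).

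In the same fit the mutant effect passed for 4452 genes in leaf blade (2084 rose, 2368 fell), 3049 in leaf sheath (1678 rose, 1371 fell) and 5470 in root (2762 rose, 2708 fell). The dye term passed for 5482 genes. These tests weigh an effect against the spread between arrays, and the labels do not say whether that includes a spread between plants. With median centring 490 genes passed in leaf blade, 46 in leaf sheath and 371 in root, and without either leaf sheath array 0 passed in leaf sheath.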

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

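The tests of the GS1;1 probe, of the transporters and of the sign assignments were chosen only after the result was seen, as was the dye test of the correlation between organs, while the tests of differences between organs and of signal strength were set earlier. Both dye tests replaced earlier ones whose outcome the dye swap or the size rule largely fixed.

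The GS1;1 probe (AK109397) showed no ratio near the size rule in RNA labelled mutant, and its highest organ ratio was 0.058. The tables argue against the same RNA in both dyes, which would leave the turned ratios of a dye swap uncorrelated, since the lowest of the 3 correlations was 0.423. A probe that reads signal without its target stays open, because its lowest signal was 1.182 times the 95th percentile of the negative controls, between the bounds of 1 and 2. An exchange of genotypes in the labels also stays open, since the ratio of 0.058 lies between the bounds of -1 and 1. A biological explanation, a truncated transcript that may still reach the probe, was not tested because the probe's place relative to the insertion is not given in the sources used here.

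Mutant effects correlated between organs at 0.364, 0.202 and 0.146. A dye bias that is equal on both arrays of a swap cancels in the averages. A remainder in proportion to the gene's dye term is argued against, since the averages correlated with that term at 0.061, 0.086 and 0.077. The largest product over a pair of organs was 0.0065. A bias shared by arrays of the same dye orientation that does not follow this term would not be seen, and it stays open. Single arrays of different organs correlated at 0.285 to 0.505 with the same dye orientation and at -0.054 to 0.043 with the opposite one. A bias that follows signal strength stays open, since the 4 groups of genes by rising signal gave 0.05, 0.094, 0.111 and 0.266 for leaf sheath and root. For the common effect, 1 of the 4 sign assignments of the 3 organs, the real one, gave as many as 1822 genes at an unadjusted p under 0.05. The highest other gave 757, and 4 assignments are too few for a share under 0.05. Since the averages correlated positively in each pair, turning the sign of 1 organ lowers the count, so this comparison restates the correlations and decides nothing. A shared effect of the genotype, or another difference between the plants compared, may also underlie the correlation and was not tested.

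Ammonium and nitrate transporters were higher in root in 3 of 20 cases, and in 1 with median centring, beside a root marker median of -0.254. Leaf tissue in the mutant root RNA is argued against, since the 100 genes highest in leaf blade over root had medians of 0.121 and 0.024 on the root arrays, below the lowest called transporter at 1.03, a test set with another bound after an earlier version (0.05 and 0.139) came out undecided. A trace of leaf tissue too small to account for the transporters stays open, since these leaf genes lay at percentile 100 of random lists matched on root signal. Light reaction genes in root also had a median of 0.099 at percentile 99.21. A larger share of root tissue that raises all root genes is argued against, since the 100 genes highest in root over leaf blade had medians of -0.281 and -0.209, and -0.458 and -0.421 with an earlier choice of genes, and dye bias of these probes is argued against, since the median of all 20 was 0.206 and 0.205 on the root arrays, where a dye bias would turn its sign. A genotype effect on nitrogen uptake genes remains a hypothesis, and a change in root age or composition, in which root-specific genes are lower, may accompany it and stays open.

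The mutant effect differed between leaf sheath and leaf blade for 2609 genes, between root and leaf blade for 4801 and between root and leaf sheath for 4072, by limma on single arrays. Without one leaf sheath array the first count went to 0 (replicate 1) or 133 (replicate 2) and the last to 286 or 309. Differences against leaf blade cannot be told apart from a difference between processing days, while leaf sheath and root share a day.

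In mutant effect, leaf sheath exceeded leaf blade by 2.34 for the calcium-binding protein CCD1 (AK111852) and 2.22 for an ankyrin-kinase (AK100268). It did so by 2.20 for Oshox6 (AK063685), 1.97 for the Ve1-like gene AK108785 and 1.92 for cadinene synthase (AK071447). It lay below leaf blade by -2.27 for the early light-inducible protein (AK062972), -1.76 for a chloroplast ribosomal RNA (AK060089), -1.62 for RRJ1 (AK100465), -1.57 for POX22.3 (AK073202) and -1.49 for a cysteine proteinase (AK072235).

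In mutant effect, root exceeded leaf blade by 3.13 for an aldolase (AK104952) and 2.91 for DDTFR19 (AK062386). It did so by 2.70 for the photosystem II 10 kD protein (AK062172), 2.29 for AK108785 and 2.24 for a CLC chloride channel (AK101523). It lay below leaf blade by -3.09 for thionin Osthi1 (AK062831), -2.69 for AK062438, -2.33 for fatty acid alpha-oxidase (AK100592), -2.24 for arginine decarboxylase (AK058573) and -1.81 for nucleoside diphosphate kinase (AK072751).

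In mutant effect, root exceeded leaf sheath by 3.45 for PBZ1 (AK071613), 3.21 for the aldolase and 2.86 for DDTFR19. It did so by 2.60 for a glucanase (AK104862) and 2.51 for ubiquitin-S27a (AK103890). It lay below leaf sheath by -3.24 for AK106022, -2.99 for thionin Osthi1, -2.61 for AK062438, -2.59 for a lipid transfer protein (AK060340) and -2.29 for an anionic peroxidase (AK104936). Of 233 other genes picked by the naming rule, 166 differed between at least 1 pair of organs.

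By the size rule, 5 genes were higher in 1 organ and lower in another. Besides PBZ1 and AK106022 these were AK062711 at -1.17 in leaf blade and 1.25 in leaf sheath, branched-chain aminotransferase 5 (AK105963) at 1.502 in leaf blade and -1.09 in root, and AK108716 at -1.04 in leaf blade and 1.11 in root.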

How the results depend on the processing

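The alternatives for the correlations between organs, list medians and named genes, and the normalization alternatives for the list tests other than processed intensities, were chosen after seeing the data. No named gene called by the size rule turned its direction under the alternatives run for it that keep both arrays. No named difference between organs did under those run for it. The direction of other genes whose call was lost was not counted. The GS1;1 probe in leaf blade and some list medians close to 0 changed sign. Under the alternatives below the cause of a change was not tested, except that leaving out arrays leaves fewer values. Calls of the size rule shared between an alternative that keeps both arrays and the reported setting had the opposite sign for 0 genes. With 1 array left out the rule itself fixes their sign. The median of all genes lay between -0.016 and 0.014 under each alternative. Signal over background limits dim probes, and the GS1;1 probe is among them. The median of all probes of a gene was not run, since each cDNA name has 1 probe and the names could not be joined to loci. Several cDNAs of the same gene may therefore count as separate genes in the lists and counts. The slide as a block was not run, since 6 slides hold 1 array each.

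The GS1;1 probe stood at 0.051 in leaf blade and 0.13 in root with processed intensities and with the series table. Median centring gave 0.028 in leaf blade and -0.228 in leaf sheath, and intensities without background subtraction gave 0.013 and -0.075.

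By the size rule, leaf blade had 92 higher and 220 lower genes with processed intensities, 92 and 219 with the series table, 25 and 68 with median centring, and 68 lower without background subtraction. Leaf sheath had 124 higher and 61 lower with processed intensities and with the series table, 19 lower with median centring, and 40 higher and 17 lower without background subtraction. Root had 69 lower with median centring. Leaving out 1 replicate gave 56 to 116 higher and 133 to 249 lower in leaf blade, 89 to 107 and 41 to 72 in leaf sheath, and 123 to 144 and 127 to 250 in root. The share of calls that were higher was 27.2%, 68.6% and 44.2% in leaf blade, leaf sheath and root. It was 46.6% in leaf blade and 53.1% in root without replicate 1, and 55.3% in leaf sheath and 33% in root without replicate 2.

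Correlations between organs with 1 replicate left out were 0.472 to 0.524 for leaf blade and leaf sheath, 0.315 to 0.35 for leaf blade and root and 0.282 to 0.293 for leaf sheath and root, where single arrays keep their dye bias. For leaf sheath and root the value was 0.139 with processed intensities, 0.2 with median centring, 0.16 without background subtraction and 0.137 without the signal filter.

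The common effect called 202 risen and 303 fallen genes with the 6 arrays as separate samples and a dye term. That fit counts the 2 arrays of an organ as independent. Under each other alternative limma called 0, with unadjusted counts of 115 to 4389 and smallest adjusted p of 0.0867 to 0.726. The lowest count, 115, came with trend and robust variance moderation and lies below the 929 that chance gives. Camera called 0 lists with an estimated correlation, 3 with processed intensities and 10 with median centring.

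In limma on single arrays, leaf blade had 170 risen and 320 fallen genes with median centring, 920 and 1079 without the dye term, and 624 to 1974 and 874 to 2247 with 1 array left out. Leaf sheath had 519 and 395 with processed intensities, 32 and 14 with median centring, 471 and 348 without the dye term, and 0 to 1555 and 0 to 1220 with 1 array left out. It had 0 without either leaf sheath array. Root had 1530 and 1446 with processed intensities, 193 and 178 with median centring, 915 and 1074 without the dye term, and 750 to 2501 and 887 to 2602 with 1 array left out.

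Differences between leaf sheath and leaf blade numbered 1343 with processed intensities, 56 with median centring, 808 without the dye term and 0 to 2265 with 1 array left out. Those between root and leaf blade numbered 3064, 112, 1586 and 2241 to 2793 in that order, and those between root and leaf sheath 1403, 0, 1130 and 286 to 3533. The dye term passed for 32 genes with processed intensities, 12893 with median centring and 2 to 2647 with 1 array left out.

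Of 390 values for named differences between organs under alternatives, 356 stayed past the threshold with their direction and 34 were no longer past it, 19 of these with median centring. Of 1167 values for named genes per organ under alternatives that keep both arrays, 801 lay within 1 SD and 366 moved by more. Leaving out 1 of 2 arrays cannot move a mean by 1 SD, so those values are not counted. Of 480 list medians, 327 lay within their spread and 153 moved by more. That spread is the SD of the medians with replicate 1 or replicate 2 left out, which are themselves among the 480. Of the 96 medians under each alternative that keeps both arrays, 70 lay within it with processed intensities. With median centring 57 did, and without background subtraction 82 did.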

Other observations

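The tests of the 3 hypotheses in this part were chosen only after the result was seen, and the lists they use leave out genes already named and members of the 32 lists.

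Several transcripts without a named product, chosen after their values were seen, had large ratios in a pair of organs. AK108619 stood at 3.29 ± 0.27 in leaf sheath and 4.49 ± 0.43 in root, and AK069119 at 3.56 ± 0.14 in leaf blade and 1.85 ± 0.19 in leaf sheath. AK065702 was lower in leaf sheath and root, at -1.20 and -2.47. Cytosolic pyruvate orthophosphate dikinase (AK065739), which forms phosphoenolpyruvate from pyruvate, was lower in leaf sheath and root at -1.20 and -1.22. Invertase AK061240, which splits sucrose, was lower in both leaf organs, at -1.16 ± 0.15 in leaf blade and -1.07 ± 0.08 in leaf sheath, the only call of its list there. With median centring and without background subtraction that list had 0 lower in either leaf organ. Alpha-amylase AK073487 was lower in root at -1.61 ± 0.21.

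Glutathione S-transferases, which conjugate toxic compounds, were higher in root for AK107435 at 1.72 ± 0.20 and AK064612 at 1.04, 2 of 51 measured and 1 with median centring, while OsGSTU10 (AK061233) was lower in leaf blade at -1.19 ± 0.05, a call lost with median centring and without background subtraction. A metallothionein (AK058529), a metal-binding protein, was higher in root at 1.21 ± 0.10, the only one called of 26 iron and metal genes, a number that 13.93% of random lists reached. With median centring 0 of that list were higher, and without replicate 2 there were 2 lower. The list's median in leaf sheath was -0.084, at percentile 0.26, and 0.002 without replicate 2. Cytochrome P450 genes in root had a median of 0.06, at percentile 99.99 of random lists, with 1 of 92 higher, but 0.016 with median centring, where 0 were higher, and 0.107 without replicate 2. In leaf sheath their median was -0.045, at percentile 0.1, and -0.102 with median centring and -0.027 without background subtraction. Heat shock protein and chaperone genes had medians of 0.037 in leaf blade, 0.051 in leaf sheath and 0.074 in root, at percentiles 97.88, 99.86 and 99.89, with 0 called. Without replicate 1 the leaf blade and leaf sheath medians were 0.018 and 0.005, and without replicate 2 the leaf blade median was 0.068. Of the 96 list medians set against random lists, 13 were below and 18 above the central 95%.

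A hypothesis was that jasmonate and defence genes share a lower level in mutant root, as thionin and lipoxygenase were among the 10 lowest named genes there. The 57 remaining genes of such a list had a median of -0.101 at percentile 0, which is in line with it for these genes, and 4 were lower with 0 higher. Another 110 of the 167 members were left out, and the fixed lists were mixed in root. Medians were -0.013 (percentile 16.39) for pathogenesis-related proteins and chitinases, with 5 lower and 2 higher, 0.007 (percentile 61.03) for WRKY factors, and -0.042 (percentile 0.62) for peroxidases, with 3 lower and 0 higher. In that order the medians were -0.046, -0.031 and -0.118 with median centring. They were -0.037, 0.017 and -0.049 without replicate 1, and 0.005, 0.013 and -0.062 without replicate 2. The 4 lower genes of the 57 were allene oxide synthase (AK107161), an enzyme of jasmonate synthesis, at -1.18 ± 0.09, the protease inhibitors AK062495 at -1.64 ± 0.24 and AK063833 at -1.38 ± 0.03, and a glucanase (AK063953) at -1.06 ± 0.06. The root marker median of -0.254 stands beside this, and a root of other age or composition could give the same pattern. An earlier version with a wider choice of genes gave percentile 0.64 over 183 genes, more than the 167 members of this list.

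A further hypothesis was that transporters of inorganic ions share a higher level in mutant root. The 42 remaining genes had a median of 0.06 at percentile 98.89, which is in line with it, although 0 passed the size rule. Members ranged from 0.81 ± 0.33 for a probe of the potassium channel subunit KOB1 (AK110894) to -0.60 ± 0.08 for the chloride channel OsCLC-1 (AK066027), and a further Sultr1-1 probe (AK106552) stood at -0.17 ± 0.15. An earlier version with a wider choice of genes gave percentile 99.95 over 73 genes, and the root marker median of -0.254 stands beside this result too.

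The last hypothesis was that genes of the cytoskeleton and of growing walls share a higher level in mutant leaf sheath. The 92 remaining genes had a median of 0.042 at percentile 99.69, which is in line with it for these genes, while the fixed lists of expansins and cell wall synthesis, at 0.024 (percentile 92.5), and of histones and cell cycle, at 0.045 (percentile 91.01), lay inside the central 95% of random lists. Medians of these 2 fixed lists were 0.004 and 0.01 without replicate 1, and 0.063 and 0.127 without replicate 2. A kinesin (AK064973), a motor protein of microtubules, was higher at 1.38 ± 0.19. Tubulin genes of the list ranged from 0.71 (AK072502) to -0.04 (AK110638), with 0 called. A leaf sheath at another stage of growth may give this pattern, and the labels do not settle which leaf was taken. An earlier version with a wider choice of genes gave percentile 99.81 over 108 genes.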
